A study of Homo sapiens with 6 samples.

How the data were processed

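Total RNA of 3 parental and 3 sorafenib-resistant Hep3B samples was extracted with silica columns and sequenced after a poly(A) library kit based on template switching, per the labels' protocols. The submitters' processing notes name the mouse builds GRCm38 and mm10. The name of the deposited file gives DESeq as the test software, without a version. The aligner and counter were not given in the sources used here. The deposited table lists human symbols, and 97.1% of its 16619 entries matched a gene of GENCODE 29, a human annotation on GRCh38. Its chromosome accessions are those of GRCh38, so coordinates are given as the table lists them on that build.

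Per the file headers, the authors deposited group means of normalized reads for each gene, a signal value with no value per library. The deposited fold is the ratio of resistant to parental mean, and the largest relative difference from that ratio was 1.21e-14. The deposited log2 value is the log2 of that fold, per the file headers. The deposited p-value came with an adjusted p that equalled a Benjamini-Hochberg adjustment over all 16619 entries within 1.33e-15. The authors also deposited gene length in bases as another value, which was not used. In parental cells 821 entries and in resistant cells 775 entries had a mean of 0.

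Comparisons rest on the authors' deposited table, with a call at an adjusted p under 0.05. The tests fixed before the data were examined needed values per library (a quasi-likelihood test of counts, or limma-trend on normalized values), so this is a departure from the plan. Genes of chromosome Y and XIST were left out, leaving 16605 entries. A first analysis used limma-trend and camera on the recovered libraries described next, and its results had been seen when the deposited table was made the main source. The rank test of gene lists was also chosen at that point.

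Each deposited mean is a sum of whole reads of 3 libraries, each multiplied by a fixed step, and the steps were read from genes with few reads. Whole reads were then solved for 16524 genes within a relative tolerance of 8e-15, with group means up to 20000 tried, and 95 genes were left without. Of means up to 1000, 100% of those above 0 had a single solution in both groups. For means over 1000, only splits with each library's value within 40% of the group mean were tried. Among those splits, 98.3% of such means in parental and 98.5% in resistant cells had a single solution. Shifted values made as decoys gave a solution in 0% of means up to 1000, and in 0.477% and 0.208% of higher means. Size factors from the steps differed from median-of-ratios factors by at most 0.0809%. On simulated reads of 1500 genes per group with means up to 1000, 100% were recovered, and higher means were not simulated. The libraries were named a to c by falling size factor within each group and could not be matched to single samples. They held 20356328, 17558498 and 15396128 reads in parental and 17123532, 15543252 and 15057283 reads in resistant cells. The 10 most counted genes took 4.30% of normalized reads in parental and 4.14% in resistant cells, and EEF1A1 led with 0.925% and 0.941%.

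Recovered reads divided by their size factors were tested with limma 3.58.1 (limma-trend) in R 4.3.3 on log2(value + 1) for genes with a mean of at least 1, with Benjamini-Hochberg adjustment. Folds on that scale understate the change of low genes. On data simulated from 16524 genes with 200 changed, this test called 86% of genes changed 1.5-fold, 98% at a fold of 2, 96% at 4 and 100% at 8, with 50 genes each for resistant against parental cells. It called 8 unchanged genes. The changed genes were not drawn from the lowest genes tested, and the simulated variance was a fixed multiple of the mean. Far fewer genes were changed than were called in the real data. The shares may therefore not hold for low or more variable genes.

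Lists of genes fixed before the data were examined, 35 with 623 members, were tested with limma's cameraPR on ranks of the signed normal deviate of the authors' p, with a preset correlation of 0.01 and genes with a mean of at least 1. A list needed 3 measured members, and 34 were tested with Benjamini-Hochberg adjustment over them. On values simulated for each gene independently and without regional shifts, 3.6% of 500 random lists of 20 genes had a p under 0.05. The rate among correlated or shifted neighbouring genes was not simulated. The same test was run on windows of 40 genes at steps of 20 along the chromosomes. Marker lists were compared as mean log2 CPM per recovered library with exact permutation tests. The pathways of the deposited annotation with 10 to 300 genes, 316 in all, were tested in the same way, and 0 passed an adjusted p of 0.05 (lowest 0.0819, alanine, aspartate and glutamate metabolism).

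The named genes are the 10 higher and 10 lower with the largest log2 ratio at a call under 0.05 and at least 5 CPM in the higher group, without overlap of the recovered values where these existed, in each list members with the smallest p, and 18 genes fixed beforehand, some of which are not reported here. Other list members given as examples were chosen after their values were seen. The ratio used log2(mean + 1), since several groups were listed at 0. That scale, the admission of genes without recovered values (CPS1), and of genes whose symbol GENCODE 29 does not hold (ARSL), were settled after the data were examined.

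A gene present on an assembled chromosome and again on another scaffold is listed in several entries. This holds for 526 symbols, and for 30 of 539 list members. The chromosomal entries of such genes had a median parental mean of 15.6 against 406 for other genes, so the levels of LDHA, CTSB, FDFT1 and SQSTM1 are uncertain. Reads of near-identical copies could not be separated in these values. Alternatives covered other scalings, pseudocounts, filters, tests and statistics for the lists, and each recovered library left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6, pandas 2.3.3 and numba 0.67.0 for the recovery.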

Results

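The series measured polyadenylated RNA by sequencing in Hep3B, a human hepatocellular carcinoma cell line, and asked how parental cells differ from cells of the same line with acquired resistance to sorafenib. Sorafenib is a multikinase inhibitor used in advanced liver cancer. There were 3 parental and 3 resistant libraries. The deposited table gives each gene's mean normalized read number in each group, with a fold and a p-value, for 16619 gene entries. Whole reads of each library were recovered from these means for 16524 of the entries, and the libraries held 15057283 to 20356328 recovered reads. Between 14576 and 14769 genes had reads in a library. The labels name no separate cultures, so the p-values measure only the spread between these samples, which may be technical. Group means below are those of the authors' deposited table, in normalized reads, and coordinates are on GRCh38.

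Resistant and parental cells differed in 49.2% of the listed genes. In the authors' deposited table, 8172 of 16605 genes passed an adjusted p of 0.05, with 4082 higher and 4090 lower in resistant cells, and 1671 of these differed by a fold of 2 or more, 815 higher and 856 lower, or 747 (363 and 384) among genes with a mean of at least 5 CPM. The gene with the largest rise from a parental level of 0 was ARSL (X, 2934521 to 2968245), an arylsulfatase, listed in the authors' deposited table at 0 in parental and 454 in resistant cells. In the other direction ETV1 (chromosome 7, 13891229 to 13991425), an ETS family transcription factor, was listed at 369.8 in parental and 0 in resistant cells of the authors' deposited table. CPS1, the mitochondrial enzyme that starts the urea cycle, fell from 39056 to 242, or 161-fold, in the authors' deposited table.

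Among the 10 genes with the largest rise, 6 were listed at 0 in parental cells. Besides ARSL these were the kinase gene PRKX at 292, the proteoglycan gene SRGN at 247, the matrix glycoprotein gene SPARC at 237, the glycosyltransferase gene GALNT6 at 129 and the sulfotransferase gene GAL3ST1 at 129 in resistant cells of the authors' deposited table. SLC12A3, the thiazide-sensitive sodium chloride cotransporter, rose from 1.65 to 904 in the authors' deposited table, and KYNU, an enzyme of tryptophan breakdown, from 2.52 to 313. Their parental means rest on 5 and 9 recovered reads, so their folds are uncertain, 549 for SLC12A3 but 1659 without parental library b, and 124 for KYNU but 651 without parental library a. ZNF831 rose 256-fold from 4.01 to 1027 in the authors' deposited table. FAM43A rose 99.5-fold from 25.7 to 2557 in the authors' deposited table. The highest adjusted p of these 10 genes in the authors' deposited table was 2.60e-47.

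Among the 10 genes with the largest fall, PTGS2, the inducible cyclooxygenase, fell from 104 to 0.322 in the authors' deposited table, and PLA2G4A, the phospholipase that releases arachidonic acid, from 952 to 17.4. IL2RB, an interleukin receptor chain, fell from 183 to 1.79 in the authors' deposited table. The resistant means of PTGS2 and IL2RB rest on 1 and 5 recovered reads, and were 0 without resistant library a for PTGS2 and without resistant library b for IL2RB. The scavenger receptor gene SCARA5 fell 217-fold from 1765 to 8.12, and the protease inhibitor gene SPINK5 104-fold from 1532 to 14.7, in the authors' deposited table. MARCOL fell from 2457 to 51.0 and GAMT, which makes creatine, from 299.6 to 3.85 in the authors' deposited table, the latter from 11 recovered reads and 1.93 without resistant library c. WFDC1 was listed at 133 in parental and 0 in resistant cells of the authors' deposited table. Some of these genes lie near each other. PTGS2 ends at 186680423 on chromosome 1 and PLA2G4A starts at 186828949, and SPINK5 ends at 148137382 on chromosome 5 and MARCOL starts at 148238525. In the recovered libraries, standard errors of the log2 fold of the named genes lay between 0.14 and 0.50 for the higher and 0.12 and 0.54 for the lower genes (limma-trend, 3 against 3 libraries, CPS1 not recovered).

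**Figure D1:**
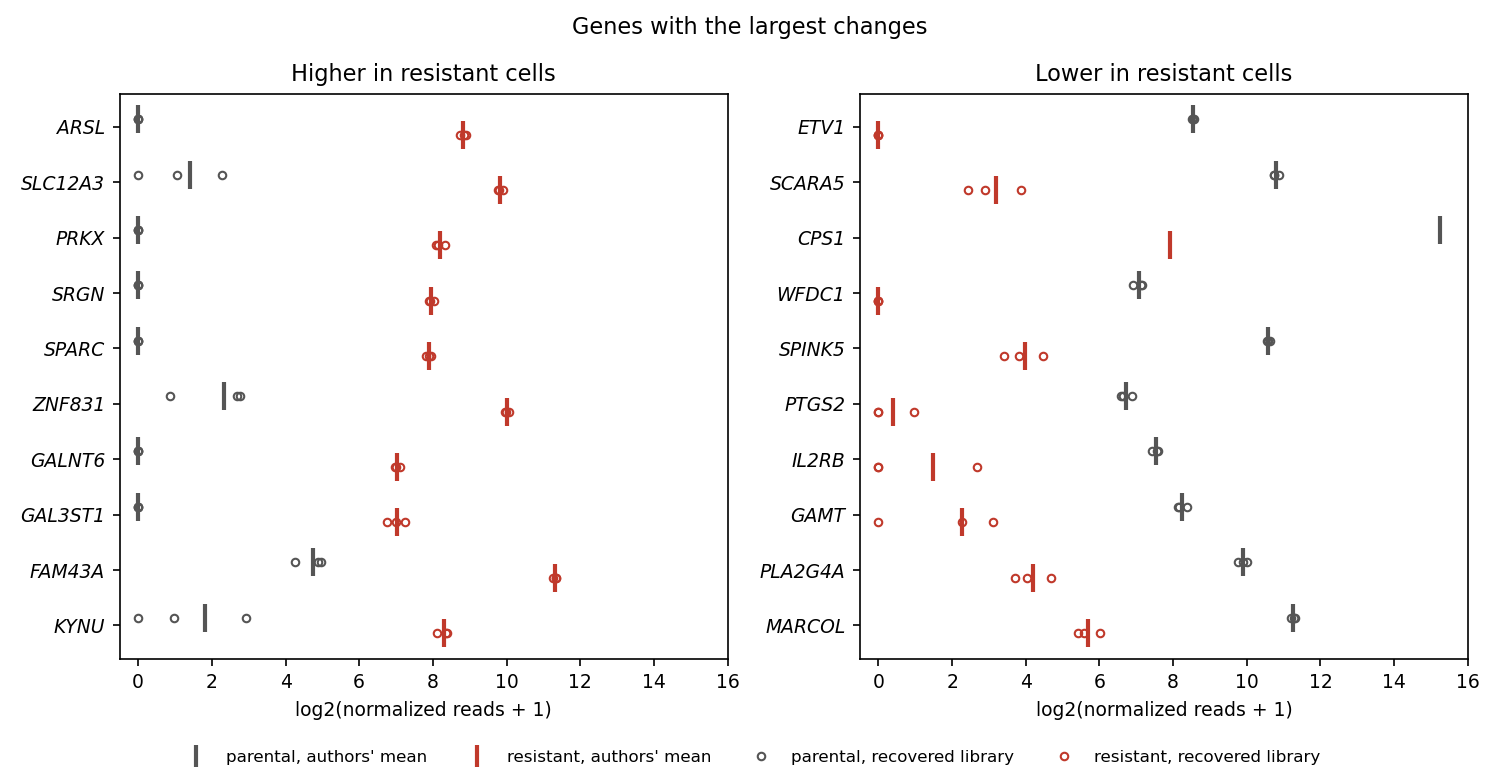
Normalized reads of the 10 genes with the largest rise (left) and the 10 with the largest fall (right) in resistant cells, on a log2(value + 1) axis. Vertical ticks are the authors' group means and open circles the recovered libraries, grey for parental and red for resistant cells, and CPS1 has group means only. ARSL was listed at 0 in parental cells and at 454 in resistant cells.

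Of the genes fixed beforehand for their roles in liver cancer and sorafenib response, 13 were measured, and AFP, ALB, GPC3, FGF19 and MT1G were not analysed here. AXL, a receptor tyrosine kinase, rose 5.50-fold from 56.0 to 308 in the authors' deposited table (adjusted p = 3.27e-54). YAP1, the Hippo pathway coactivator, rose from 4696 to 6719.7, and the intermediate filament gene VIM from 12339.7 to 14764, in the authors' deposited table. The sorafenib target BRAF rose from 1384 to 1649.7 in the authors' deposited table. SLC7A11, the cystine importer, fell 4.18-fold from 1767 to 423, and GPX4, the lipid peroxidase, from 2848 to 1849, in the authors' deposited table. GPX4 had a log2 fold of -0.62, no larger a fall than that of its neighbourhood. The window of 80 genes around it on chromosome 19 (281043 to 2478259) had a median log2 ratio of -0.73 relative to all genes. In the authors' deposited table EGFR fell from 11352 to 6119.9, MET from 8733 to 5783 and CD44 from 4921 to 3916. Neither the drug efflux pump gene ABCB1 (124 and 126, adjusted p = 0.962) nor CDH1 (26.7 and 28.6, adjusted p = 0.991) passed the test in the authors' deposited table. In the recovered libraries the standard errors of the 13 measured genes' log2 folds lay between 0.025 and 0.29 (limma-trend).

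Inflammatory genes were mostly lower in resistant cells. Of 15 measured NF-kappaB and inflammatory genes, 12 were lower and 1 higher in the authors' deposited table, with the same counts adjusted over the list alone, and the list fell against other genes (rank test of limma's cameraPR, adjusted p = 0.00845). With camera on the recovered libraries the list had adjusted p = 0.00234, and the call was lost at adjusted p = 0.447 with an estimated correlation. The chemokine gene CXCL8 was listed at 24.8 in parental and 0 in resistant cells of the authors' deposited table. In the same comparison of the authors' deposited table, CCL2 fell from 78.1 to 3.57, the adhesion molecule gene ICAM1 from 1259 to 414, TNFAIP3 from 1951 to 674 and IL32 from 5616 to 2212. The resistant mean of CCL2 was 2.13 without recovered resistant library b. TNFAIP3 and NFKBIA, which fell from 1164 to 694 in the authors' deposited table, encode inhibitors of NF-kappaB. The cytokine gene IL6 rose from 9.18 to 54.2 in the authors' deposited table.

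Output genes of the ERK pathway were mostly higher. Of 16 measured, 11 were higher and 2 lower in the authors' deposited table, with the same counts adjusted over the list alone (cameraPR, adjusted p = 0.0313, and adjusted p = 0.577 with an estimated correlation). In the authors' deposited table the ETS factor genes ETV4 and ETV5 rose from 336 to 740.4 and from 419 to 909. Negative regulators of the pathway were among the higher genes of the authors' deposited table, with DUSP4 rising from 815 to 1316 and SPRED1 from 348 to 659. MYC fell from 6731 to 5953 and EPHA2 from 2710.2 to 1905 in the authors' deposited table. The call was lost with p-derived values in place of ranks (adjusted p = 0.0528) and, with camera, without recovered resistant library a (adjusted p = 0.0616). Of 6 measured sorafenib kinase targets, 4 were higher and 1 lower in the authors' deposited table (adjusted p = 0.199), among them FGFR1, which rose from 630.5 to 1523. Receptor tyrosine kinases and ligands moved both ways, with 7 of 17 higher and 6 lower in the authors' deposited table (adjusted p = 0.730). ERBB2 rose from 1067 to 2327 and ERBB3 from 291 to 801 in the authors' deposited table.

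Mesenchymal genes were mostly higher, although the list missed the threshold. In the authors' deposited table, 13 of 23 were higher and 5 lower (cameraPR, adjusted p = 0.0826). Fibronectin, FN1, rose 29.4-fold from 19.2 to 564 and TGFBI from 56.7 to 337 in the authors' deposited table. CDH2 rose from 211 to 757 and S100A4 fell from 2474 to 421 in the authors' deposited table. Of 16 epithelial junction genes 7 were higher and 5 lower in the authors' deposited table (adjusted p = 0.636), and the tight junction gene CGN rose from 44.5 to 1106. Of 14 TGF-beta and BMP response genes 8 were higher and 5 lower in the authors' deposited table (adjusted p = 0.205), with TGFB1 rising from 251 to 833. Of 16 YAP and TEAD targets 6 were higher and 6 lower in the authors' deposited table (adjusted p = 0.836), and CCN1 and CCN2 both fell, CCN1 from 1438 to 686 and CCN2 from 616 to 256. Of 13 Wnt and beta-catenin targets 2 were higher and 5 lower in the authors' deposited table (adjusted p = 0.691). Of 11 oncofetal and progenitor markers 5 were higher and 5 lower in the authors' deposited table (adjusted p = 0.730). The progenitor surface genes ANPEP and THY1 rose from 212 to 2929 and from 3.38 to 149.9 in the authors' deposited table, and EPCAM fell from 814 to 377.

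The measured hepatocyte genes changed singly. The list of hepatocyte transcription factor and secreted protein genes held 25 genes, of which only 11 were measured, so it says little about the rest. Of these 11 genes 2 were higher and 2 lower in the authors' deposited table (cameraPR, adjusted p = 0.836). The transcription factor genes CEBPA and HNF4A rose from 104 to 1179 and from 195 to 606 in the authors' deposited table, and FOXA1 fell from 131 to 48.4. Of 14 coagulation and complement genes 5 were higher and 2 lower in the authors' deposited table (adjusted p = 0.606), and the complement gene C3 fell from 2820.2 to 577.

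Antioxidant genes were mostly higher and integrated stress response genes mostly lower, although neither list passed the rank test. Of 23 targets of NRF2, the regulator of antioxidant genes, 14 were higher and 6 lower in the authors' deposited table (cameraPR, adjusted p = 0.0919). SRXN1 rose from 2817 to 7502, OSGIN1 from 354 to 1748 and GCLM from 2116 to 6016 in the authors' deposited table, while NQO1 fell from 11834 to 7002. KEAP1, which encodes the repressor of NRF2 and was chosen after its values were seen, fell from 651 to 25.4 in the authors' deposited table. Of 23 integrated stress response genes 13 were lower and 5 higher in the authors' deposited table. That list missed the threshold in the rank test (adjusted p = 0.0619) and passed it with camera on the recovered libraries (adjusted p = 0.0386, and adjusted p = 0.548 with an estimated correlation). The serine synthesis genes PHGDH and PSAT1 fell from 5369.6 to 3280.3 and from 8054 to 4962 in the authors' deposited table, and DDIT3 rose from 153 to 282. Of 19 ferroptosis regulators 5 were higher and 11 lower in the authors' deposited table (adjusted p = 0.205), and the ferritin gene FTL fell from 32963 to 19535. Of 3 metallothionein genes 1 was lower, MT1E, from 436 to 217 in the authors' deposited table (adjusted p of the list = 0.730). Endoplasmic reticulum chaperone genes were 7 higher and 6 lower of 17 (adjusted p = 0.862), and heat shock and immediate early genes 3 higher and 5 lower of 11 (adjusted p = 0.391), in the authors' deposited table. Of 18 interferon-stimulated genes 10 were higher and 3 lower in the authors' deposited table (adjusted p = 0.114), with IFIT1 rising from 346 to 741 and BST2 falling from 4560.2 to 2148.

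Among metabolic lists, cholesterol synthesis genes were mostly lower, 12 of 20 against 4 higher in the authors' deposited table (cameraPR, adjusted p = 0.0826). HMGCS1 was among the higher genes and rose from 8730.2 to 11742 in the authors' deposited table. Glycolysis genes were 6 higher and 9 lower of 21 (adjusted p = 0.836), fatty acid synthesis genes 3 higher and 3 lower of 12 (adjusted p = 0.685) and fatty acid oxidation genes 5 higher and 5 lower of 15 (adjusted p = 0.730) in the authors' deposited table. Nuclear genes of the respiratory chain were 6 higher and 5 lower of 21 (adjusted p = 0.991), and hypoxia response genes 7 higher and 6 lower of 20 (adjusted p = 0.748), in the authors' deposited table. Drug transporters were 5 higher and 3 lower of 14 (adjusted p = 0.730) and drug-metabolising enzymes 2 higher and 5 lower of 13 (adjusted p = 0.636) in the authors' deposited table. The mitochondrial genes of the respiratory chain were not analysed here.

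DNA replication genes were mostly lower and mitosis genes mostly higher, although neither list passed the test. Of 19 DNA replication genes 3 were higher and 11 lower (cameraPR, adjusted p = 0.0919), and of 19 mitosis genes 12 were higher and 4 lower (adjusted p = 0.190), in the authors' deposited table. The helicase gene MCM4 fell from 11008 to 6865 and CCNE1 from 904 to 425, and the mitotic kinase gene AURKA rose from 3803 to 5463, in the authors' deposited table. Apoptosis regulators were 8 higher and 6 lower of 17 (adjusted p = 0.730) and autophagy and lysosome genes 9 higher and 2 lower of 19 (adjusted p = 0.304) in the authors' deposited table. BCL2 rose from 191 to 468 and BIRC3 fell from 1328 to 440.5 in the authors' deposited table. In all, 2 of 34 lists passed the threshold in the rank test and 0 with an estimated correlation. With 3 against 3 libraries the latter version has few degrees of freedom, so its 0 says little about single lists. Counts adjusted over the list alone equalled those over all genes except for 1 or 2 more genes in the hypoxia, integrated stress, NRF2, ferroptosis, drug transporter, apoptosis, interferon and heat shock lists. Median, mean and test differed in sign for hepatocyte genes (median log2 ratio 0.12, mean -0.14, test up), glycolysis (-0.0018, 0.17, down) and drug transporters (-0.030, 0.24, up). The same held for sorafenib targets (0.20, -0.12, up), receptor tyrosine kinases (0.19, -0.056, up), nuclear respiratory chain genes (-0.010, -0.026, up) and endothelial markers (0.58, -0.073, down).

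**Figure D2:**
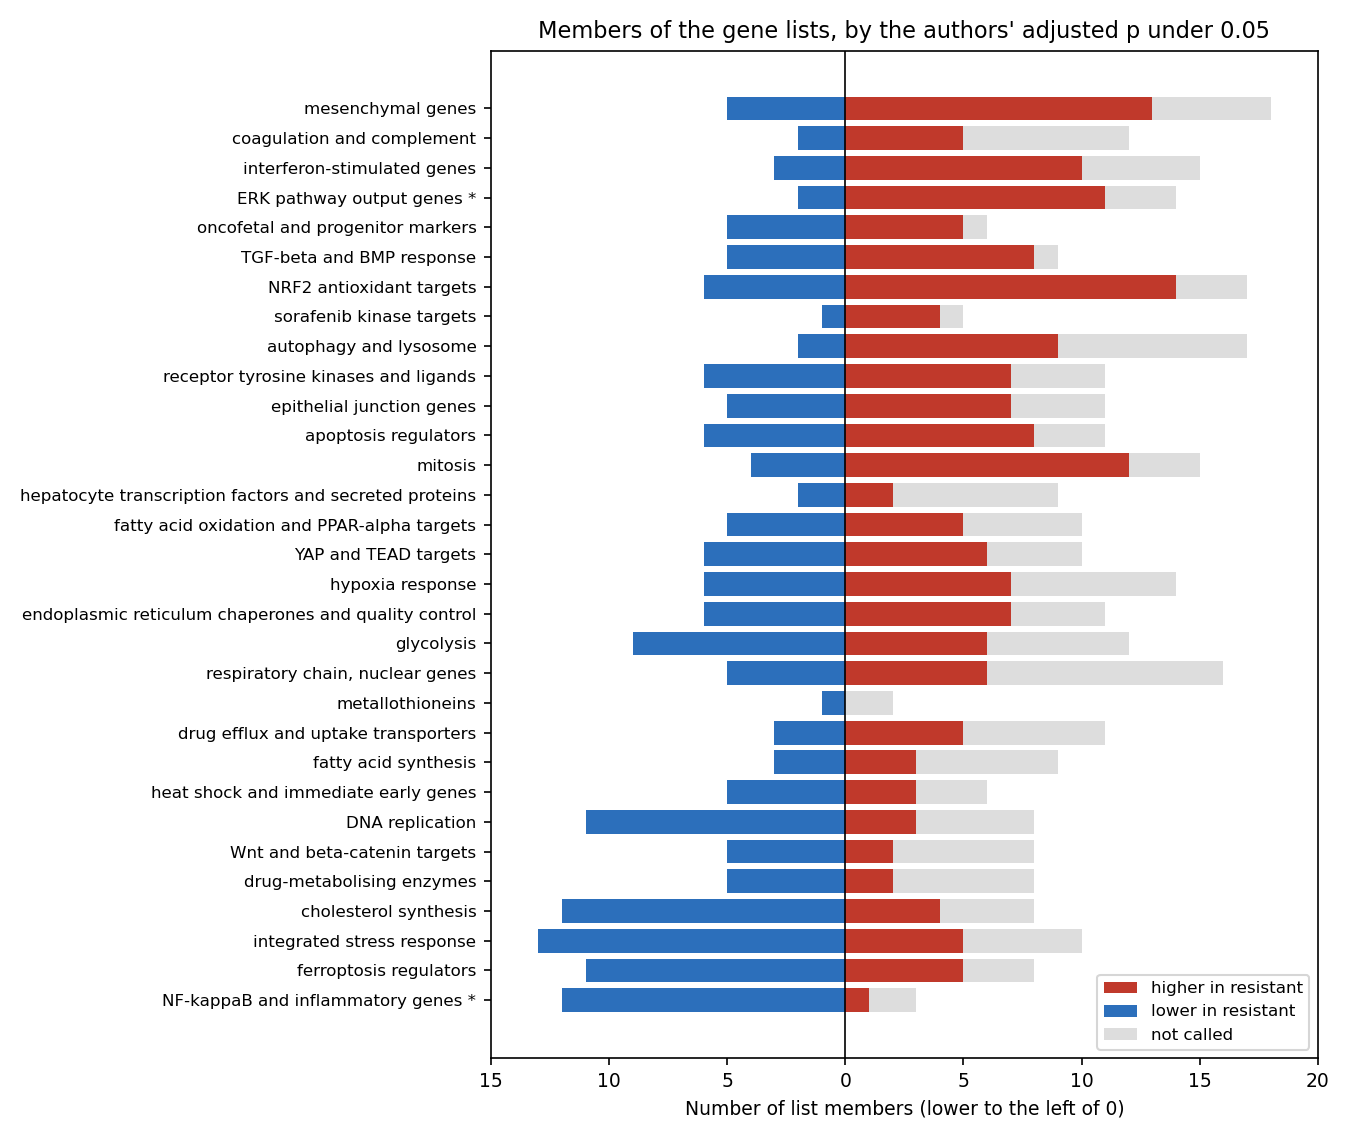
Number of measured members of each gene list that were higher (red), lower (blue, to the left of 0) or not called (grey) in resistant cells at an adjusted p under 0.05 in the authors' deposited table, ordered by median log2 ratio. Asterisks mark the 2 lists past the threshold in the rank test, with NF-kappaB and inflammatory genes at 12 lower of 15 and ERK pathway output genes at 11 higher of 16.

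Markers of other cell types were compared in the recovered libraries. The mean log2 CPM of 7 fibroblast markers was 1.95 ± 0.042 (SD, n = 3) in parental and 2.58 ± 0.024 (SD, n = 3) in resistant libraries (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 libraries allow). It was 1.46 ± 0.11 and 1.10 ± 0.0066 for 7 leukocyte markers (exact p = 0.1) and 1.31 ± 0.078 and 1.14 ± 0.13 for 6 endothelial markers (exact p = 0.2, SD, n = 3 each), and the adjusted values were 0.15, 0.15 and 0.2. In the rank test against other genes the adjusted p was 0.391 for fibroblast, 0.390 for leukocyte and 0.900 for endothelial markers. Of the fibroblast markers, MFAP5 rose from 417 to 3907 and FBLN1 fell from 7914 to 5655 in the authors' deposited table, and the collagen gene COL3A1 was listed at 0 and 2.80 without passing (adjusted p = 0.241, 0.966 in place of 2.80 without recovered resistant library b). Fibroblast values and mesenchymal genes were both mostly higher in resistant libraries, and leukocyte values and inflammatory genes both mostly lower. With only 2 groups, lists that differ in the same direction always do so in the same libraries. Whether other cell types contributed to these lists therefore cannot be told from it.

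Neighbouring genes moved together along chromosomes. Of 672 windows of 40 neighbouring genes, 341 (50.7%) passed the threshold, 158 higher and 183 lower in resistant cells relative to the median of all genes (cameraPR, adjusted p under 0.05). The median log2 ratio of whole chromosomes was -0.43 for chromosome 8, -0.42 for 16, -0.42 for 19, -0.40 for 21 and -0.31 for chromosome 1, each relative to all genes. On chromosome 16, 396 of 670 genes were lower and 46 higher in the authors' deposited table, and 31 of its 32 windows were past the threshold and lower. Most other chromosomes lay a little above the median of all genes, among them 22 at 0.19, 17 at 0.17, 11 at 0.15 and 2 at 0.12. Chromosomes 4 and 9 were near it, at 0.019 and 0.014. The lower chromosomes pull down the median of all genes, so small positive shifts, and windows counted as higher, need not be rises. The largest rise of a region was on X, where 109 genes from 2.83 to 46.91 Mb had a median of 0.50 and the 351 genes after them 0.073, split where the parts differed most. A window on chromosome 19 that starts with DNMT1 and ends with ODAD3 had a median of -0.80, and it covers KEAP1 and ICAM1. With windows of 80 genes 198 of 317 passed, 104 higher and 94 lower.

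**Figure D3:**
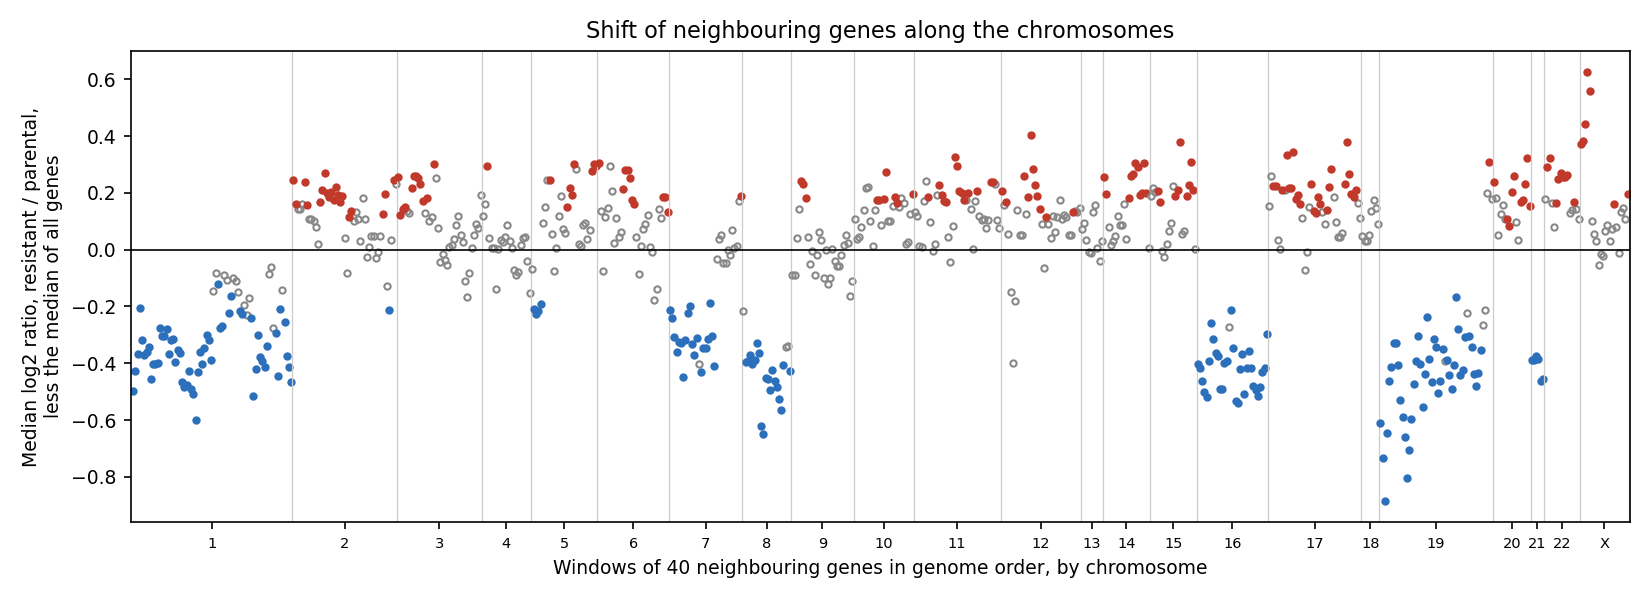
Median log2 ratio of resistant to parental cells, less the median of all genes, in windows of 40 neighbouring genes ordered along chromosomes 1 to 22 and X. Red and blue points are windows higher or lower at an adjusted p under 0.05 and open grey points did not pass. The windows of chromosomes 8, 16, 19 and 21 lie mostly under 0, and chromosomes have medians down to -0.43.

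The recovered libraries of a group resembled each other more than those of the other group. Pearson correlations of log2 values across 14641 genes, which are not independent replicates, were 0.987 to 0.989 within groups and 0.952 to 0.954 between groups. No pair was as close as counting error alone, with a median chi-square per gene of at least 0.833 against 0.455 by counting error. A limma-trend test of the recovered libraries called 8991 of 14641 genes, 4531 higher and 4460 lower. It shared all 8088 calls of the authors' deposited table among those genes, with 0 in the opposite direction, and made 903 further calls. The recovered libraries were solved from the deposited means, so the shared direction was largely fixed in advance and is no separate evidence. The values of both groups did not overlap for 9538 genes, or 65.1%, where chance gives 10%.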

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

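All alternatives on recovered libraries, and the statistics for gene lists, were chosen after seeing the data. They included the choice of the deposited table and of ranks, made after limma-trend and camera on recovered libraries, which call 8991 genes and 3 lists, had been run and seen. No paired analysis was possible because the columns are group means and the recovered libraries carry no replicate number. The edgeR quasi-likelihood test, its size factor variant and its fold test and the DESeq2 test were not run, and limma-voom on the recovered reads was run in their place. The replicate block was not run either. For the changes of gene lists and single genes in this part, the cause was not tested.

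The count of genes was 8369 to 9063 under limma-trend and limma-voom with other scalings, pseudocounts and filters and with each library left out, against 8172. Library totals gave 9038, with 52.3% of calls higher. Against a fold of 1.5, which tests for a larger change, 1840 genes were called, 885 higher and 955 lower. With at least 5 CPM, which leaves fewer genes, 747 differed by a fold of 2 or more, 363 higher and 384 lower.

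The number of lists past the threshold, 2 with ranks, was 7 with values in place of ranks, 4 with log2 ratios, 3 with camera on recovered libraries, 0 with an estimated correlation and 28 with fry, which compares no list with other genes. It was 1 to 5 with camera and a library left out, the lowest without resistant library a.

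Adjusted p-values that newly passed with values in place of ranks were 0.0159 for oncofetal and progenitor markers, 0.0201 for mesenchymal genes, 0.00290 for integrated stress response, 0.0117 for NRF2 antioxidant targets, 0.0163 for TGF-beta and BMP response and 0.0117 for cholesterol synthesis. The value was 0.0528 for ERK pathway output genes, no longer past the threshold. Directions turned, with adjusted p 0.984 for coagulation and complement, 0.984 for endoplasmic reticulum chaperones and quality control and 0.984 for respiratory chain, nuclear genes. With log2 ratios, new passes had 0.0445 for mesenchymal genes and 0.0129 for interferon-stimulated genes, and turned directions 0.914 for glycolysis, 0.993 for drug efflux and uptake transporters, 0.951 for respiratory chain, nuclear genes and 0.914 for endothelial markers. Less the median of 81 neighbouring genes, 0.0158 for interferon-stimulated genes passed, and directions turned with 0.884 for endoplasmic reticulum chaperones and quality control, 0.833 for metallothioneins, 0.923 for receptor tyrosine kinases and ligands, 0.923 for mitosis and 0.884 for endothelial markers. Camera on recovered libraries gave 0.0386 for integrated stress response as a new pass, and turned directions with 0.672 for glycolysis and 0.962 for respiratory chain, nuclear genes. With an estimated correlation calls were lost with 0.577 for ERK pathway output genes and 0.447 for NF-kappaB and inflammatory genes, and directions turned with 0.759 for glycolysis and 0.985 for respiratory chain, nuclear genes. With fry, new passes were 0.00341 for hepatocyte transcription factors and secreted proteins, 3.39e-05 for oncofetal and progenitor markers, 8.75e-06 for mesenchymal genes, 0.00171 for epithelial junction genes, 1.22e-05 for integrated stress response, 1.08e-04 for NRF2 antioxidant targets, 1.62e-04 for ferroptosis regulators, 0.0302 for metallothioneins, 0.00235 for drug efflux and uptake transporters, 0.00649 for drug-metabolising enzymes, 1.95e-04 for sorafenib kinase targets, 0.00220 for receptor tyrosine kinases and ligands, 0.00920 for Wnt and beta-catenin targets, 2.85e-04 for TGF-beta and BMP response, 4.92e-04 for DNA replication, 5.55e-04 for mitosis, 4.95e-04 for autophagy and lysosome, 3.95e-04 for cholesterol synthesis, 0.0205 for fatty acid synthesis, 0.00341 for fatty acid oxidation and PPAR-alpha targets, 1.75e-04 for interferon-stimulated genes, 4.92e-04 for heat shock and immediate early genes, 4.97e-08 for fibroblast markers and 0.00648 for leukocyte markers. Its direction turned with 8.56e-04 for coagulation and complement, 0.655 for glycolysis, 0.00117 for apoptosis regulators and 0.146 for respiratory chain, nuclear genes.

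With a library left out, camera's adjusted p ranged over 0.0367 to 0.0852 for mesenchymal genes, 0.662 to 0.713 for glycolysis, 0.0319 to 0.0606 for integrated stress response, 0.0319 to 0.0616 for ERK pathway output genes, 0.0349 to 0.0852 for cholesterol synthesis, 0.819 to 0.949 for respiratory chain, nuclear genes and 0.819 to 0.985 for endothelial markers. The log2 fold ranged over -0.044 to 0.10 for ABCB1, -0.095 to 0.30 for CDH1 and -0.058 to 0.014 for MT2A. None of these genes passed the authors' test. Depth limits genes of few reads, and 95 genes had no recovered libraries.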

Other observations

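In all, 17 genes were listed at 0 in parental cells and at 30 or more in resistant cells, and 7 the other way round, counting those already named such as ARSL, PRKX and ETV1. In the authors' deposited table the protease gene CTSC was listed at 0 in parental and 93.8 in resistant cells, the protease inhibitor gene SERPINB5 at 0 and 80.7, the coagulation inhibitor gene TFPI at 0 and 55.4, and the growth factor gene FGF9 at 0 and 39.7. In the other direction ANOS1 was listed at 55.7 and 0, and ANO3 at 44.4 and 0, in the authors' deposited table. These genes were chosen after their values were seen.

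Genes of drug handling moved both ways. In the authors' deposited table the uptake transporter gene SLCO2B1 rose from 14.3 to 311 and SLC22A3 from 436 to 874, and the efflux transporter gene ABCC3 rose from 338 to 878 while ABCG2 fell from 78.2 to 28.0. CYP3A5 fell from 165 to 41.4, and the xenobiotic receptor gene AHR and its target CYP1A1 fell from 1548 to 560.3 and from 78.6 to 9.95, in the authors' deposited table. POR, the electron donor of cytochrome P450 enzymes, rose from 2579.7 to 5639 in the authors' deposited table.

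All tests below were chosen after the results were seen. Splitting the 6 recovered libraries 3 against 3 can be done in 10 ways, and 1 of these, the real one, gave 8991 genes (limma-trend) against a highest of 0 in the others, too few splits for a share under 0.05.

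Chromosomes 1, 8, 16, 19 and 21 were mostly lower in resistant cells, with a median log2 ratio of -0.31 or below, though not along their full length, as 58 of 72 windows of chromosome 1 and 44 of 51 of chromosome 19 were lower and 1 of chromosome 19 was higher. With a trend on GC content removed, the smallest of these shifts was still -0.31, and without the genes that differed by a fold of 2 or more, 163 windows were still past the threshold and lower. Each recovered resistant library had the shift, the smallest being -0.30. A candidate explanation is a difference in the number of chromosome copies, and chromosome 7, split at the point where its parts differed most, had -0.32 before and 0.054 after, a step of -0.38. The split point was chosen from the same values and no DNA was measured, so that explanation cannot be told apart from regional regulation.

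On the short arm of X, 5 neighbouring genes (GYG2, ARSD, ARSL, MXRA5 and PRKX, 2828712 to 3713649) were listed at 0 in parental cells, in a part of X with a higher median (109 genes, median log2 ratio 0.50 relative to all genes). Single genes of that part went both ways. In the authors' deposited table ANOS1 was listed at 55.7 in parental and 0 in resistant cells, and ARHGAP6 at 41.7 and 0. SHROOM2, which lies between them, was listed at 0 and 44.2. GYG2 and MXRA5 were also near the floor in resistant cells of the authors' deposited table, at 3.79 (adjusted p = 0.0452) and 3.18 (adjusted p = 0.0882). No shuffle of 14128 genes in 10000 gave a run as long (permutation p = 1e-04, the smallest they can give), nor did any shuffle of 11296 genes with a group mean of at least 30, where the run was ARSD, ARSL and PRKX (permutation p = 1e-04). Reads of ARSL and PRKX could be mapped, with at least 425 and 273 normalized reads in each recovered resistant library. These genes were chosen for such values, so this is no separate test of mapping over the segment. Resistant libraries held 2410 reads of the 5 genes, mostly of ARSL, PRKX and ARSD, against 0 in parental libraries, and in parental cells the segment may be missing or silent, which cannot be told apart here without DNA.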
